A study of Saccharomyces cerevisiae with 21 samples.

How the data were processed

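Processed signals deposited by the authors were used, with no raw array files. The deposited table holds 9335 probe sets of the Affymetrix YG-S98 array for 21 arrays as linear signal, in the intensity unit the authors' software (GCOS, version 1.2 where stated) gives. The authors describe values under 12 as set to 12 for the S- and P-limited and the mutant arrays, yet the deposited table holds lower values for these arrays. Each array was scaled to a common 2% trimmed mean signal (150.2), values under 12 were raised to 12 and log2 was taken. Of the probe sets 60 were controls, 6504 matched 1 gene, 328 matched several genes and 2443 had no annotation. For the 315 genes with several probe sets the one with the highest mean signal was kept, which gave 5656 genes. The 195 genes at the floor on every array were left out, and 5461 were tested. Gene names follow the S. cerevisiae reference annotation R64.

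Means of the 7 groups were fitted with limma 3.58.1 in R 4.3.3 over all 21 arrays, with a moderated t statistic per contrast and p values adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05 and a fold of at least 2. Folds are ratios of geometric means, signals are arithmetic means with SD, and ± after a log2 value is the standard error of the fit. Where any array of the lower group was at the floor, the fold is given as a lower bound. The difference of the mutant effects was the contrast of the N-limited minus the C-limited effect. A gene was specific to a limitation when it was called in one direction against each of the other 4 wild-type groups, with adjustment within each comparison.

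Groups of genes were tested with camera in limma at its preset correlation of 0.01, at an adjusted p under 0.05 within each contrast, and again with a correlation estimated for each list and with fry. The 26 lists were glycogen synthesis, glycogen breakdown, glycogen regulators, trehalose synthesis, trehalose breakdown, glucose phosphate interconversion (together the reserve carbohydrate genes), Msn2/4 stress targets, nitrogen catabolite repression, sulfur assimilation, phosphate regulon, zinc regulon, glucose-repressed carbon metabolism, glucose-excess transport and glycolysis, anaerobic growth, respiratory chain, sterol synthesis, single-copy ribosomal proteins, ribosome biogenesis, general amino acid control, autophagy, inositol and choline phospholipid synthesis, iron regulon, pyrimidine synthesis, meiosis and sporulation, a-cell and pheromone genes, and alpha-cell genes. They were written from general knowledge of yeast. Some members had no probe set of their own and were not measured, among them DUR1,2, SEO1, PHO11, PHO12, SFC1, ARG5,6, ARN2, SPO11, SPO13, HOP1 and MF(ALPHA)2.

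Groups, contrasts, thresholds, lists and the rule for naming genes were set before the data were examined. By that rule the text could name MSN2, MSN4 and URA3 as checks of the labels and all reserve carbohydrate genes. From every other list it could name up to 4 called genes with the largest change and up to 2 with the smallest adjusted p among those not called. Per comparison it could also name the 5 highest and 5 lowest called genes with no overlap between the arrays of the groups, the 10 largest differences of the mutant effect, and for each limitation the 5 specific genes with the largest smallest fold. The genes that place the doubtful array and members that make up a count of at most 5 were chosen after their values were seen. Culture data and the probe sets with several or no genes were left out of all tests, except that all probe sets were tested as an alternative.

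The procedure was tested on simulated data with the same number of arrays. Of genes given a log2 change of 1, 1.5, 2 and 3 it called 38%, 80%, 92% and 94% between N and C limitation, 50%, 76%, 84% and 94% between P and S limitation, 32%, 56%, 80% and 92% for the difference of mutant effects and 18%, 64%, 82% and 88% as specific to Zn limitation. At most 8 unchanged genes were called in a simulated comparison. Of 20 raised lists 20 were called, and of 500 unchanged lists 1. Noise was simulated independently for each gene, with no gene-wise effect of deposit. The rate for unchanged lists therefore does not carry over to real lists, whose genes can vary together.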

Results

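Transcript levels were measured on 21 yeast genome arrays, each hybridised with RNA from a chemostat culture, titled anaerobic, of Saccharomyces cerevisiae. The arrays form 7 groups of 3. Independent replicate cultures are stated for all groups but the C-limited wild type, for which nothing is said, and the meaning of the b that ends 5 array codes in the S- and P-limited and mutant groups is not given. In 5 groups the wild type was limited for carbon (C, as glucose), nitrogen (N), sulfur (S), phosphorus (P) or zinc (Zn), and in the other two a strain titled as the double mutant of MSN2 and MSN4, genes of stress transcription factors (msn2 msn4), was limited for C or N. All cultures ran at a dilution rate of 0.10 per h and pH 5.0, and residual glucose was aimed at 17 g/L except under C limitation, so each comparison with C limitation also sets high against low glucose. The deposited growth text of the N-limited wild-type cultures also describes sparging with air and glucose as the limiting nutrient. They were taken as anaerobic and N-limited from their titles and medium, which bears on all their values. The trimmed mean signal as deposited was 235 to 251 on the C-limited, 247 to 311 on the N-limited and 398 to 466 on the Zn-limited wild-type arrays, and 150.1 to 150.2 on the other 12. After scaling, 24.9% to 33.4% of the probe sets of an array lay at the floor of 12. The ratio of actin signal at the 3' end to the 5' end, a measure of RNA integrity, was 1.05 to 1.20 on the C-limited and 1.18 to 1.23 on the N-limited wild-type arrays, 1.30 to 1.37, 1.22 to 1.41 and 1.31 to 1.47 in S, P and Zn limitation, and 1.24 to 1.42 and 1.18 to 1.67 in the C- and N-limited mutant. The S-, P- and Zn-limited and the C-limited mutant arrays thus all lay above the C-limited wild type they are compared with. The number of arrays, 3 per group, limits the precision of every value below. The C-, N- and Zn-limited wild-type arrays are each a deposit of their own, and the S- and P-limited and both mutant groups share another. In the comparisons made here deposit and group therefore cannot be told apart, except between P and S limitation and between the mutant groups.

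MSN2 signal lay between 12.0 and 13.7 on the 6 mutant arrays and between 58.0 and 147 on the wild-type arrays. URA3, carried on a plasmid in the mutant, lay between 1087 and 2473 against 30.5 to 82.4. MSN4 was not at the floor on the mutant arrays: it lay between 34.5 and 55.6, against 47.3 to 153 on the wild-type arrays, and was not called (log2 -0.91 ± 0.22 in C and -0.87 ± 0.22 in N limitation). The arrays therefore show the loss of MSN2 transcript and not that of MSN4, which is taken from the titles. The array labelled C-limited msn2 msn4 replicate 1 stood apart from its group. DAL5, an allantoate permease gene of nitrogen catabolite repression, read 1337 there, against 83.5 and 109 on the other two arrays of the group, and RGI2, a respiratory growth gene, read 12 against 302 and 225. Across 580 genes that separate C- from N-limited wild type in a fit of the wild-type arrays alone, with C at 0 and N at 1, this array lay at 0.695, the N-limited mutant arrays at 0.684 to 0.806 and the other C-limited mutant arrays at 0.237 and 0.290. Across 38 genes specific to N limitation in that fit its position was 0.729, against -0.0398 and -0.0372. This array, called the doubtful array from here, was kept as labelled. For comparisons that use it, the counts of genes called by limma are also given without it, but not every group test or later check.

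**Figure D1:**
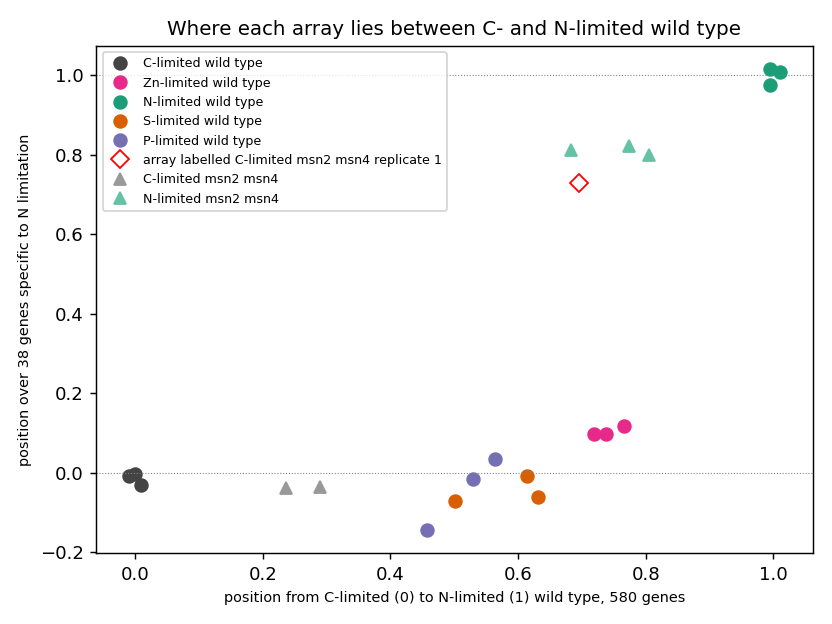
Each point is 1 array, placed on the x axis by its position between C-limited (0) and N-limited (1) wild type over 580 genes and on the y axis by its position over 38 genes specific to N limitation (both without unit, with genes called in a fit of the wild-type arrays alone). The array labelled C-limited msn2 msn4 replicate 1 (open diamond) lies at 0.695 and 0.729, beside the N-limited mutant arrays and away from the other C-limited mutant arrays.

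N limitation was compared with C limitation to find transcripts that follow the limiting nutrient at one growth rate. Genes of nitrogen catabolite repression, which take up and use poor nitrogen sources, stood higher: 14 of 22 measured members rose, 1 fell (MEP3, an ammonium permease) and 7 were not called. DAL5 (YJR152W) had a mean signal of 2337 ± 250.0 (SD, n = 3) against 56.4 ± 14.0, a rise of 42.2-fold (log2 5.40 ± 0.65, standard error). This standard error takes in the spread of the doubtful mutant array, which is not compared here. With that array out of the fit the standard error of DAL5 was 0.27 even for 3 arrays against 2. DAL80, a repressor of the same genes, rose 27.5-fold, the general amino acid permease gene GAP1 27.2-fold and the proline oxidase gene PUT1 23.6-fold. Respiratory chain genes stood lower, with 16 of 25 falling and none rising: COX5A fell 6.13-fold, and CYC1 (YJR048W), cytochrome c, was at least 20.5-fold lower, at the floor on every N-limited array. Of the Msn2/4 stress targets, 11 of 27 rose, such as YGP1 (5.64-fold), ALD2 (at least 6.83-fold) and HSP42 (4.18-fold), and MRK1 fell 16.9-fold. Among genes of glucose-repressed carbon metabolism, 6 of 20 fell, with the invertase gene SUC2 down 12.0-fold, while the malate synthase gene MLS1 was at least 17.9-fold higher. HXT3 (YDR345C), a low-affinity hexose transporter gene, rose 13.1-fold. In all, limma called 567 genes, 357 higher and 210 lower. As groups against the other genes (camera), the adjusted p was 7.3e-06 for nitrogen catabolite repression, 5.3e-12 for the respiratory chain, 1.7e-04 for the stress targets and 0.0034 for glucose-repressed metabolism. The adjusted p was 0.30, 0.22, 0.22 and 0.22 with an estimated correlation, and 0.0082, 0.0082, 0.12 and 0.12 when the doubtful mutant array also left the fit. The split was 264 higher and 304 lower after quantile normalisation, 178 and 405 after scaling to a common median, and 693 and 153 in the values as deposited.

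**Figure D2:**
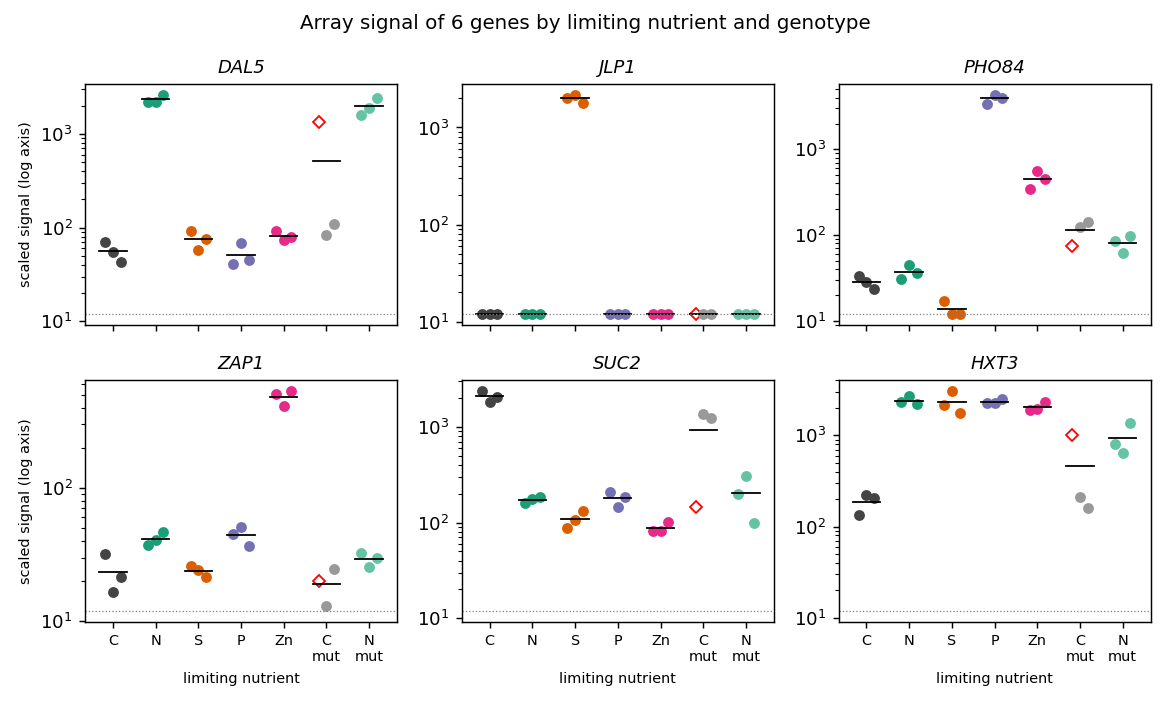
Scaled array signal (log y axis, no unit) of 6 genes by limiting nutrient, with wild-type groups first and the msn2 msn4 groups last; points are arrays, bars group means of 3 and the dotted line the floor of 12. DAL5 is high in N limitation, JLP1 in S, PHO84 in P, ZAP1 in Zn and SUC2 in C limitation, HXT3 is low in C-limited wild type, and the open diamond is the array labelled C-limited msn2 msn4 replicate 1.

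Under S limitation the sulfur assimilation list stood higher than under C limitation, with 22 of 26 measured genes rising and none falling. JLP1 (YLL057C), a sulfonate dioxygenase gene, had a signal of 2007 ± 189 (SD, n = 3) and was at the floor on all C-limited arrays, so it was at least 167-fold higher. BDS1, a sulfatase gene, rose at least 90.4-fold (log2 at least 6.50, standard error 0.38), the cysteine transporter gene YCT1 45.6-fold (log2 5.51 ± 0.26) and SOA1 at least 22.3-fold (log2 at least 4.48, standard error 0.26). Outside the list, PDC6, a pyruvate decarboxylase gene, rose 95.4-fold (log2 6.58 ± 0.65). Respiratory chain genes were lower, 18 of 25, among them COX5A (5.66-fold) and COX7 (4.12-fold), as was CYC1, at least 20.5-fold lower and at the floor in S limitation. SUC2 fell 19.4-fold, the maltose permease gene MAL11 16.0-fold and the gluconeogenesis gene PCK1 7.42-fold, and HXT3 rose 12.3-fold. Of the 27 Msn2/4 stress targets 9 rose, with HSP26 up 6.34-fold and YGP1 up 4.45-fold, and MRK1 fell 22.9-fold. The arginine synthesis genes ARG1 and ARG3 fell 3.88-fold and 4.20-fold. The test called 592 genes, 255 higher and 337 lower. For sulfur assimilation the adjusted p was 6.2e-33, and 1.5e-06 with an estimated correlation. For the respiratory chain it was 2.2e-10, with an adjusted p of 0.41 with an estimated correlation (0.0082 without the doubtful mutant array), and for the stress targets 0.0031, with an adjusted p of 0.36 with an estimated correlation. Other scalings gave 294 higher and 302 lower after quantile normalisation, 325 and 280 after scaling to a common median, and 84 and 1645 in the values as deposited.

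P limitation raised the phosphate regulon above its level in C limitation: 14 of 16 measured genes rose and none fell. PHO84 (YML123C), the high-affinity phosphate transporter gene, went from 28.4 ± 4.92 to 3923 ± 473 (SD, n = 3), 139-fold (log2 7.12 ± 0.25). SPL2 rose at least 86.6-fold (log2 at least 6.44, standard error 0.31), the glycerophosphoinositol permease gene GIT1 at least 59.0-fold (log2 at least 5.88, standard error 0.30) and the sodium phosphate transporter gene PHO89 38.4-fold (log2 5.26 ± 0.42). In the same cultures 12 of 26 sulfur assimilation genes fell and none rose. SUL1 (YBR294W), a sulfate permease gene, was at the floor on all P-limited arrays and at least 90.7-fold lower, SUL2 fell 8.93-fold and the S-methylmethionine permease gene MMP1 at least 9.45-fold. Respiratory chain genes fell in 22 of 25 cases, with COX5A down 7.36-fold and CYC1 at least 20.5-fold lower, and SUC2, PCK1 and the aldehyde dehydrogenase gene ALD4 fell 11.7-fold, 8.02-fold and 4.53-fold. HXT3 rose 12.8-fold and the cell wall gene DAN4 3.56-fold, and MAL11 and MEP3 fell 29.6-fold and 9.97-fold. limma called 637 genes (215 higher, 422 lower). The adjusted p was 5.7e-32 for the phosphate regulon and 1.9e-04 for sulfur assimilation, and 6.3e-06 and 0.028 with an estimated correlation. The respiratory chain had an adjusted p of 9.3e-11, and of 0.38 with an estimated correlation (0.0067 without the doubtful mutant array). The counts were 269 higher and 326 lower after quantile normalisation, 329 and 274 after scaling to a common median, and 64 and 2049 in the values as deposited.

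Zn limitation raised 17 of 20 measured zinc regulon genes above C limitation and lowered none. ZAP1 (YJL056C), the zinc-responsive activator gene, rose from 23.2 ± 7.93 to 480.1 ± 63.9 (SD, n = 3), 21.3-fold (log2 4.41 ± 0.24). ZPS1 rose 45.4-fold (log2 5.50 ± 0.34), the alcohol dehydrogenase gene ADH4 18.9-fold (log2 4.24 ± 0.20), and VEL1 was at least 87.2-fold higher, being at the floor in C limitation. YOR387C, a paralogue of VEL1 outside the list, was at least 233-fold higher. Phosphate genes moved too: 8 of 16 rose, with PHO89 up 29.3-fold, PHM8 at least 15.4-fold and PHO84 15.7-fold, and PHM6 fell. The methionine permease gene MUP1 and STR3 rose 9.06-fold and 10.1-fold and SUL1 fell 10.1-fold, so that sulfur assimilation had 8 genes higher and 4 lower of 26. Of the Msn2/4 stress targets 10 rose, with YGP1 up 11.1-fold and HSP26 7.21-fold, and MRK1 fell 24.3-fold. The respiratory chain had 17 of 25 genes lower, such as COX5A (5.53-fold) and SDH2 (3.61-fold). The hexose transporter genes HXT6 and HXT7 fell 4.48-fold and 4.27-fold, and HXT1 was at least 25.4-fold higher. The test called 806 genes, 494 higher and 312 lower. Adjusted p values were 3.9e-19 for the zinc regulon, 8.3e-05 for the phosphate regulon, 5.5e-09 for the respiratory chain and 0.014 for the stress targets; with an estimated correlation the adjusted p was 2.7e-04, 0.058, 0.29 and 0.29. Without the doubtful mutant array the respiratory chain had an adjusted p of 0.014 with an estimated correlation. Scaled otherwise, the counts were 409 higher and 445 lower after quantile normalisation, 349 and 531 after scaling to a common median, and 2280 and 64 in the values as deposited.

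Genes were called specific to one limitation when they passed both thresholds in one direction against each of the other 4 wild-type groups. In Zn limitation 144 genes were specific (127 higher, 17 lower), led by YOR387C at 2804, at least 233-fold above the next group, VEL1, HAB1, ZPS1 and RTC4, and they included 11 of the 20 zinc regulon genes. C limitation had 117 (81 higher, 36 lower), with RGI2 at least 36.1-fold, MRK1 16.9-fold and SUC2 11.7-fold higher, HXT4 at least 15.7-fold and HXT3 11.1-fold lower, and 12 of 25 respiratory chain genes higher. S limitation had 56 (44 higher, 12 lower): JLP1 was at least 167-fold and BDS1 40.2-fold above the next group, the amino acid permease gene AGP3 at least 19.1-fold, and 17 of 26 sulfur assimilation genes were higher. P limitation had 54 (35 higher, 19 lower), with SPL2 (21.9-fold), the acid phosphatase gene PHO3 (17.5-fold) and PHM6 (12.0-fold) higher, 12 of 16 phosphate regulon genes higher and 9 sulfur assimilation genes lower. N limitation had 39 (32 higher, 7 lower), with DAL5 (28.6-fold), DAL80 (15.0-fold), MLS1 (at least 11.2-fold) and the oligopeptide transporter gene OPT2 (10.9-fold) higher and 9 of 22 genes of nitrogen catabolite repression among them. Each fold is the smallest against the other 4 groups. A difference between deposits could make a gene specific to C, N or Zn limitation. For S and P limitation, which share a deposit, it could not do so alone. The counts therefore do not rank the limitations.

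P and S limitation were compared within a single deposit. Sulfur assimilation genes were lower in P limitation, 24 of 26, and none was higher. SUL1 read 2147 ± 64.6 (SD, n = 3) in S limitation and was at the floor in P limitation, at least 179-fold lower, and JLP1 was at least 167-fold lower in the same way. YCT1, BDS1 and PDC6 fell 103-fold, 68.6-fold and 55.7-fold. Of the phosphate regulon 14 of 16 genes were higher and none lower: PHO84 rose at least 289.6-fold (log2 at least 8.18, standard error 0.25), SPL2 at least 87.2-fold (log2 at least 6.45, standard error 0.31) and GIT1 at least 78.7-fold (log2 at least 6.30, standard error 0.30). PHO3, outside the list, rose 82.1-fold (log2 6.36 ± 0.32) to 3854 ± 386. In total 231 genes were called, 104 higher and 127 lower. The adjusted p was 3.0e-56 for sulfur assimilation and 1.3e-45 for the phosphate regulon, and 4.3e-08 and 3.4e-07 with an estimated correlation. With only the 6 arrays compared in the fit, 145 genes were called. After scaling to a common median 127 were higher and 113 lower.

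Reserve carbohydrate metabolism is the subject of the series, and 32 genes of glycogen and trehalose metabolism were measured. In N limitation TSL1 (YML100W), a subunit gene of the trehalose synthase complex, rose 2.61-fold (log2 1.38 ± 0.23), from 90.0 ± 7.73 to 234 ± 9.24 (SD, n = 3). The trehalase gene NTH1 and the genes TPS3 and PIG2 also rose (2.32-fold, 2.16-fold and 2.42-fold), but after scaling to a common median their log2 changes were 0.93, 0.83 and 0.99 and no longer passed. The calls of the glycogen phosphorylase gene GPH1 (log2 1.44 ± 0.47) and the hexokinase gene HXK1 (log2 -1.46 ± 0.51) ended whichever of the 6 arrays was left out (adjusted p 0.054 to 0.11 and 0.078 to 0.13). GAC1, a targeting subunit gene of the glycogen synthase phosphatase, fell in S (6.58-fold), P (10.1-fold) and Zn limitation (5.59-fold). HXK1 fell in S (4.44-fold) and Zn limitation (7.30-fold). In P limitation its call ended with any array left out (adjusted p 0.058 to 0.13). The fit behind these HXK1 values holds the doubtful mutant array, which is not compared here. With that array out of the fit HXK1 was called in N and P limitation, and its standard error was 0.21 for 3 arrays against 3. Zn limitation also lowered the branching enzyme gene GLC3 3.29-fold (log2 -1.72 ± 0.30) and the glucokinase gene GLK1 2.48-fold (log2 -1.31 ± 0.28), neither of which passed in the values as deposited, and raised PIG2 4.50-fold (log2 2.17 ± 0.28). Over all genes 5 reserve genes were higher and 1 lower in N limitation, 0 and 5 in S, 1 and 3 in P, and 2 and 6 in Zn limitation, the same counts as when adjusted over the list alone. Between P and S limitation limma called 0 of the 32, of which 8 had an unadjusted p under 0.05. As groups, trehalose synthesis was higher in N limitation (adjusted p 0.012; adjusted p = 0.22 with an estimated correlation) and glycogen synthesis lower in Zn limitation (adjusted p 0.014; adjusted p = 0.091 with an estimated correlation). Across these 4 comparisons and the 2 of the mutant described next, 19 of the 32 genes were called at least once.

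**Figure D3:**
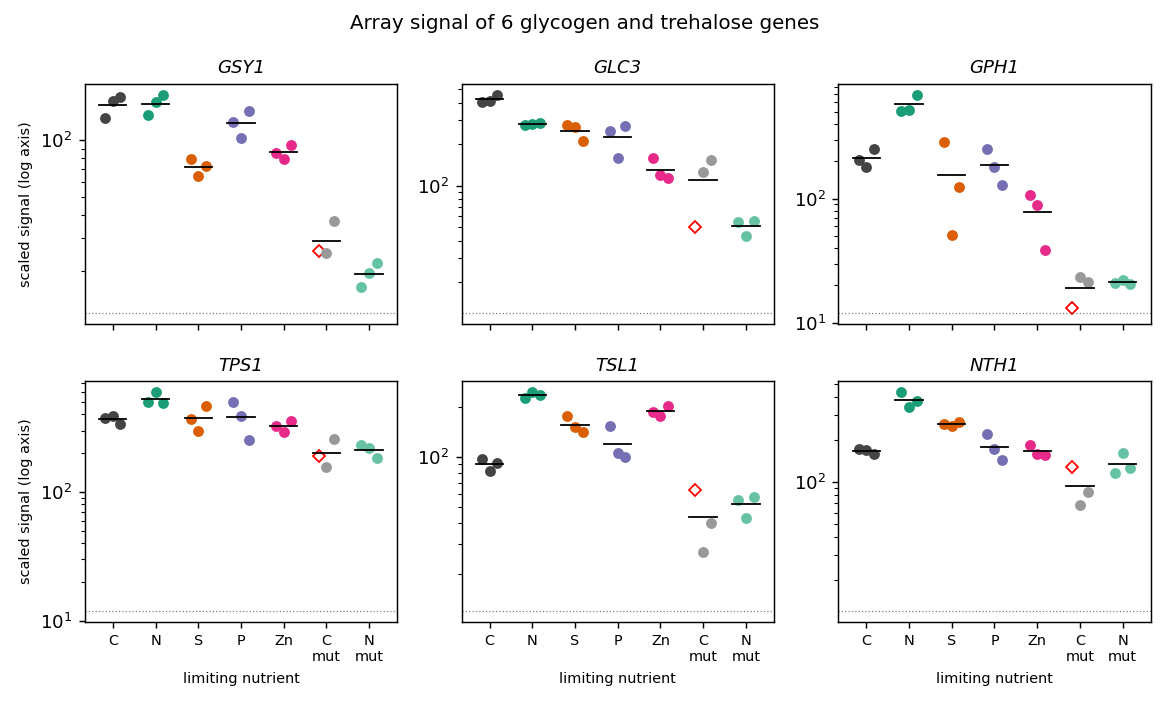
Scaled array signal (log y axis, no unit) of 6 reserve carbohydrate genes by limiting nutrient and genotype; points are arrays, bars group means of 3, the dotted line the floor of 12 and the open diamond the array labelled C-limited msn2 msn4 replicate 1. GPH1 reads 576 in N-limited wild type and 21.2 in the N-limited mutant.

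The strain titled msn2 msn4 was compared with wild type to find which transcripts differ between them. Under C limitation glycogen genes were lower in the mutant. GPH1 (YPR160W), glycogen phosphorylase, fell 11.3-fold (log2 -3.50 ± 0.47), from 213 ± 36.3 to 19.2 ± 5.31 (SD, n = 3), and without the doubtful array by a log2 change of -3.25. The glycogen synthase gene GSY1 fell 5.32-fold (log2 -2.41 ± 0.18), and by -2.33 without that array. GLC3 fell 4.29-fold (log2 -2.10 ± 0.30) and the debranching enzyme gene GDB1 3.28-fold (log2 -1.71 ± 0.30), with log2 changes of -1.61 and -1.89 without it. Of the glycogen synthesis list 4 of 5 genes fell with all arrays (adjusted p 1.7e-05; 0.0047 with an estimated correlation) and 3 without the doubtful array (7.3e-07; 0.0020). Of the 32 reserve genes 10 fell and none rose, or 12 and 1 adjusted over the list alone; without the doubtful array 8 fell, or 10 adjusted over the list alone. Of the Msn2/4 stress targets 5 of 27 fell, with DCS2 down 6.33-fold (log2 -2.66 ± 0.16), and SSA4 rose (adjusted p 0.0095, and 0.26 with an estimated correlation); without the doubtful array 5 fell and none rose (2.9e-05; 0.077), and without C-limited mutant replicate 2 the group's adjusted p was 0.31. Outside these lists MAL11 fell (log2 -4.32 ± 0.18) and NCA3 rose 5.23-fold (log2 2.39 ± 0.40). MAL11 read 40.9 over the mutant arrays and 42.3 in S- and P-limited wild type of the same deposit. For MAL11 deposit, nutrient and genotype therefore cannot be told apart. PHO5, an acid phosphatase gene at the floor on all wild-type arrays, was at least 9.11-fold higher. limma called 220 genes (112 higher, 108 lower), 141 without the doubtful array (118 shared), 492 without replicate 2 and 215 without replicate 3. With only these 6 arrays in the fit 22 genes were called, and of the genes named GPH1, GSY1, DCS2, MAL11, NCA3 and PHO5 kept the call and GLC3 and GDB1 lost it. The values as deposited gave 17 higher and 1294 lower.

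Reserve genes were also lower in the mutant under N limitation. GPH1 fell 26.9-fold (log2 -4.75 ± 0.47), from 576 ± 101 to 21.2 ± 0.644 (SD, n = 3), GSY1 fell 8.08-fold (log2 -3.01 ± 0.18) and GLC3 5.49-fold (log2 -2.46 ± 0.30). All 4 measured trehalose synthesis genes fell: TSL1 4.55-fold, TPS3 2.80-fold, the synthase gene TPS1 2.51-fold and the phosphatase gene TPS2 2.30-fold, whose log2 change of -1.20 was -0.93 after scaling to a common median. NTH1 fell 2.90-fold and the phosphoglucomutase gene PGM2 5.23-fold. Of the 32 reserve genes 16 fell and 1 rose, the same counts as when adjusted over the list alone. The rise, of SGA1, ended with any of the 6 arrays left out (adjusted p 0.067 to 0.12). The doubtful array, not compared here, widened its standard error to 0.51. With that array out of the fit the standard error of SGA1 was 0.28 and its adjusted p 0.0011. That 16 genes fell here and 10 in C limitation does not show different effects: the direct test of the difference called TPS2 alone of the 32, and PIG2, TPS2 and HXK1 without the doubtful array. Of the Msn2/4 stress targets 13 of 27 fell and none rose, with DCS2 (7.75-fold), YGP1 (5.64-fold) and HSP12 (4.48-fold) among them. Outside the lists EGO4, RTC3 and YMR090W fell 15.5-fold, 8.94-fold and 12.3-fold, SPC25 rose 5.05-fold, and PHO5 was at least 9.44-fold higher. In total 428 genes were called, 128 higher and 300 lower. The adjusted p was 1.8e-04 for glycogen synthesis, 1.8e-04 for trehalose synthesis and 1.5e-07 for the stress targets, and 0.020, 0.059 and 0.028 with an estimated correlation. Of the other reserve lists, glycogen breakdown had 2 of 3 genes lower, glycogen regulators 3 of 11, trehalose breakdown 1 of 3 and glucose phosphate interconversion 3 of 6. The higher and lower counts were 219 higher and 201 lower after quantile normalisation, 273 and 134 after scaling to a common median, and 15 and 2768 in the values as deposited.

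**Figure D4:**
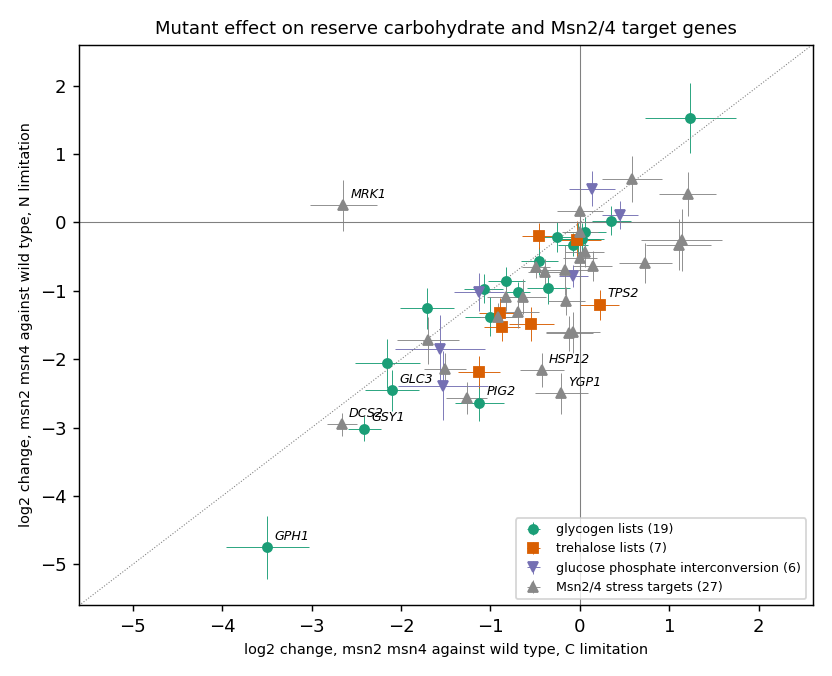
Log2 change between msn2 msn4 and wild type in C limitation (x axis) and N limitation (y axis) for the measured members of the reserve carbohydrate and Msn2/4 target lists, with standard errors as bars and the line of equal change dotted. GPH1 lies at -3.50 and -4.75, GSY1 at -2.41 and -3.01, and MRK1 at -2.64 and 0.25. The x values include the array labelled C-limited msn2 msn4 replicate 1, without which MRK1 lies at -1.99 on the x axis.

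The mutant effects under the 2 limitations shared 59 lower genes, where independent lists would share 5.93, and 24 higher genes against 2.63. Without the doubtful array they shared 45 lower and 12 higher genes, against 4.28 and 1.76. Both mutant groups share a deposit, and both wild types come from others. A deposit effect would therefore enter both lists, and an overlap above that of independent lists does not by itself show an effect of genotype. The 24 higher genes were not compared within the deposit. GPH1, GSY1, GLC3, GDB1, GAC1, TSL1 and DCS2 were lower under both limitations with all arrays and without the doubtful one. A direct test of the difference between the effects (N minus C) called 82 genes, 26 with a higher and 56 with a lower effect in N limitation. The C- and N-limited wild types are separate deposits, so a difference between these deposits could also enter this test. MAL11 differed by 2.69 ± 0.26 on the log2 scale, as it fell more in C than in N limitation. Its signal was 884 in C-limited and 117 in N-limited wild type, and 37.9 in the N-limited mutant. For MAL11 a mutant effect that depends on the nutrient is therefore not shown. The amino acid permease gene BAP2 differed by 2.73 ± 0.36 and MEP3 by 2.71 ± 0.42. YGP1 fell by more in N limitation, with a difference of -2.29 ± 0.42. The agglutinin subunit gene AGA2 differed by -1.34 ± 0.23 and the lysine synthesis gene LYS20 by 1.51 ± 0.24. Of the 32 reserve genes only TPS2 passed (log2 -1.43 ± 0.31), or 2 genes adjusted over the list alone. Without the doubtful array PIG2, TPS2 and HXK1 passed (-1.81 or lower, -1.36 and -1.26), or 4 genes over the list alone. The PIG2 value is a bound, as an N-limited mutant array was at the floor. The call of TPS2 ended in 6 of the 12 cases of an array left out (adjusted p up to 0.074). Among the Msn2/4 stress targets 3 genes had a lower and 1 a higher effect in N limitation (adjusted p 4.0e-04; adjusted p = 0.18 with an estimated correlation). Without the doubtful array 135 genes were called, 72 of them shared with the 82. The count was 44 without C-limited wild-type replicate 2, 49, 54 and 43 without N-limited wild-type replicates 1, 2 and 3, and 51 and 39 without N-limited mutant replicates 2 and 3. Scaled otherwise the counts were 49 higher and 53 lower after quantile normalisation, 52 and 25 after scaling to a common median, and 18 and 111 in the values as deposited.

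N and C limitation were also compared within the mutant, whose groups share a deposit. With all arrays as labelled, limma called 3 genes. ADY4 (log2 1.51 ± 0.20) and SDL1 (1.29 ± 0.22) were higher and the amino acid permease gene TAT2 (-2.11 ± 0.34) lower in N limitation, all lower bounds since the lower group had arrays at the floor. ADY4 lost the call with a floor of 50 or of 1, and SDL1 and TAT2 lost it when any array but the doubtful one was left out (adjusted p up to 0.22). The count was 1 without C-limited replicate 2 and without N-limited replicates 1 and 2. Without the doubtful array the test called 282 genes, 108 higher and 174 lower. Then DAL5 rose by a log2 of 4.34, GAP1 by 4.36 and OPT2 by 5.77, SUC2 changed by -2.84, and RGI2, at the floor on all N-limited arrays, fell by at least 4.44. In that fit 12 of 22 genes of nitrogen catabolite repression rose and 20 of 25 respiratory chain genes fell (adjusted p 5.0e-30 and 1.5e-24; 8.2e-05 and 0.0011 with an estimated correlation). With all arrays none of these genes was called, and the adjusted p of the groups was 4.0e-17 and 7.3e-15, or 0.28 and 0.33 with an estimated correlation. Of the genes called without it, 65 higher and 77 lower genes were also called between N- and C-limited wild type, where independent lists would share 7.22 and 6.88.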

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

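The tests of the array labelled C-limited msn2 msn4 replicate 1 were chosen after its position was seen, and the splits of the arrays were set before.

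The msn2 msn4 effect differed between N and C limitation for 82 genes by a direct test of the difference. The C- and N-limited wild types are separate deposits, so deposit as well as nutrient could enter these differences. The largest differences (log2, N minus C, with the effects in C and N limitation in brackets) were RPR1 at least 3.14 (-2.22 and at least 0.91), MRK1 2.90 (-2.64 and 0.25), SNR4 2.83 (-1.64 and 1.19), BAP2 2.73 (-2.70 and 0.04), MEP3 2.71 (-2.19 and 0.52), MAL11 2.69 (-4.32 and -1.63), RTC3 -2.47 (-0.69 and -3.16), YEA4 -2.37 (0.94 and -1.43), YRO2 -2.34 (1.48 and -0.86) and RSO55 2.31 (-0.73 and 1.58). The RPR1 values are bounds since N-limited wild-type arrays were at the floor. RPR1 and SNR4 encode noncoding RNAs. All of these were still called without the doubtful array. Their differences were then at least 2.76 for RPR1, 2.25 for MRK1, 2.58 for SNR4, 2.54 for BAP2, 2.80 for MEP3 and 2.57 for MAL11. For RTC3, YEA4, YRO2 and RSO55 they were -2.25, -2.74, -2.53 and 2.62. Of 100 drawn splits of genotype within each limitation, 7 gave a count as large, the real one included, with a highest of 1019, so chance is not excluded for the count of 82. The 6 other large splits kept all N-limited arrays together and exchanged 1 pair of C-limited arrays, and in 5 of them the genotypes of one limitation were turned round, which makes the difference of the effects a sum of what both limitations share. These 5 point to a structure of the samples, the mutant effect itself. The sixth, with 253 genes, exchanged C-limited mutant replicate 1 for C-limited wild-type replicate 3 without such a turn, and what sets it apart was not tested.

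Between N and C limitation in the mutant 3 genes were called. Of the 10 splits of these 6 arrays, too few for a share under 0.05, 3 gave as many, with a highest of 75. That split set the array labelled C-limited replicate 1 with N-limited replicates 1 and 2, which points to a structure of the samples, the C-limited array that lies with the N-limited ones.

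This array was weighed as the first pattern. A culture with glucose in excess but without N limitation is argued against by its position of 0.729 over the N-specific genes, where S-, P- and Zn-limited arrays lay between -0.145 and 0.117. An effect that goes with array codes ending in b is argued against by the other 4 such arrays, which differed from their groups by a mean of -0.0857. A mixture with RNA of a C-limited culture is argued against by a share of N-limited RNA of 1.00 (0.977 to 1.03) over 78 genes lower in N limitation, while 69 genes higher in N limitation gave 0.878 (0.802 to 0.957), a shortfall that a mixture would have shown in both sets. RNA of an N-limited culture under this label remains a candidate explanation, since the array lay at 0.695 on the axis, its nearest array was N-limited mutant replicate 1 (r = 0.977), and MSN2 and URA3 read as in the mutant. No N-limited mutant array lay with the C-limited ones (lowest 0.684), so an exchange with one of them has no partner. Apart from the glucose excess no biological explanation was tested.

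On Zn-limited wild-type replicate 2 the bacterial control probe sets Dap, Lys, Phe and Thr read 115, 30.3, 26.6 and 37.2, a signal in probe sets that no comparison uses. The highest values on the other 20 arrays were 6.40, 7.33, 10.9 and 4.10, and no explanation of this signal was tested.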

How the results depend on the processing

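The settings with array codes ending in b, and the removal of C-limited mutant replicate 1 from comparisons without its group, were chosen after seeing the data, and all others before.

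With the values as deposited, 1729 genes were called in S, 2113 in P and 2344 in Zn against C limitation, 1311 and 2783 between mutant and wild type in C and N limitation, 129 for the difference of these effects, 53 as specific to C and 731 to Zn limitation, and 30 reserve genes. The cause is the lack of scaling between deposits: the median over all genes was then 0.30, -0.70, -0.81 and 0.86 for N, S, P and Zn limitation, -0.66, -0.99 and -0.32 for the mutant comparisons, and with the trimmed mean -0.16 in P limitation, -0.14 for the N-limited mutant and -0.12 for the difference. With a common median it was -0.13 in N and -0.15 in Zn limitation. A floor of 50, which leaves fewer genes and smaller folds, gave 310, 376, 391 and 504 genes for N, S, P and Zn against C limitation, 122 and 212 for the mutant, 1 between the mutant groups, and 22 and 85 specific to N and Zn limitation. A floor of 1 gave 49 for the difference of the mutant effects. Genes with a group mean of at least 100 gave 361 for N limitation, 261 for the N-limited mutant, 5 between the mutant groups and 91 specific to Zn limitation. All probe sets gave 5 between the mutant groups and 347 between P and S limitation, and a prior variance that follows the mean signal gave 5 between the mutant groups.

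With only the groups compared in the fit, limma called 22 genes for the C-limited mutant, 145 between P and S limitation and 0 between the mutant groups, where 320 genes had an unadjusted p under 0.05, while N against C limitation gave 575 and the N-limited mutant 405. Adjusted p alone gave 1283, 1206, 1399 and 1594 for N, S, P and Zn limitation, 416 and 1013 for the mutant, 403 between P and S limitation, and 251, 114, 87, 103 and 303 specific to C, N, S, P and Zn limitation. Left out of the comparisons, C limitation no longer narrowed the N-specific genes, and they numbered 65. An estimated correlation called 14 list shifts of the 79. The code ending in b as a covariate gave 143 for the difference of effects and 12 between the mutant groups, and without the 5 such arrays 279. The replicate number as a block moved no count by more than 1.5 times. Among list shifts of the difference of effects, glucose-excess transport and glycolysis reversed to -0.321 with quantile normalisation (adjusted p 0.79) and the respiratory chain to 0.0319 without the 5 arrays (adjusted p 0.94). Where no cause is named, the cause was not tested.

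Leaving out 1 array at a time gave 492 to 581, 514 to 644, 514 to 713 and 747 to 815 genes for N, S, P and Zn against C limitation and 212 to 272 between P and S limitation. The mutant gave 141 to 492 in C limitation, lowest without C-limited mutant replicate 1 and highest without replicate 2, and 313 to 458 in N limitation. The difference of effects ranged over 39 to 135, lowest without N-limited mutant replicate 3, and the comparison of the mutant groups over 1 to 282, both highest without C-limited mutant replicate 1. Specific genes numbered 95 to 118, 33 to 49, 52 to 65, 51 to 62 and 126 to 155 for C, N, S, P and Zn. Without C-limited mutant replicate 1, 19 reserve genes and 73 list shifts were called. Over all settings the genes that may be named kept their side of the threshold in 17967 cases and crossed it in 646 (no longer called) and 563 (newly called). None that was called in the main or the other setting changed direction. A change of direction in a gene called in neither was counted as kept. On an array 24.9% to 33.4% of probe sets lay at the floor, where folds are lower bounds.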

Other observations

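The tests of the genes lower in both mutant groups and of PHO5 were chosen after these results were seen, and the splits of the arrays were set before.

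Members of lists outside the main nutrient responses were called too, in several cases without a list shift at the estimated correlation. In Zn limitation 4 of 8 iron regulon genes rose, with TIS11 up at least 12.3-fold and the iron permease gene FTR1 3.16-fold (adjusted p 0.019; adjusted p = 0.46 with an estimated correlation), and 3 of 9 meiosis and sporulation genes rose, the kinase gene IME2 at least 2.75-fold from the floor. The pheromone gene MF(ALPHA)1 rose 5.98-fold there, 1 of the 3 measured alpha-cell genes. In P limitation 3 of 8 a-cell and pheromone genes rose against C limitation, the agglutinin gene AGA1 6.13-fold (adjusted p 1.8e-04; adjusted p = 0.017 with an estimated correlation), and 3 of 12 genes of glucose-excess transport and glycolysis rose (adjusted p 0.0011; adjusted p = 0.39 with an estimated correlation). In the N-limited mutant URA3, which its plasmid carries, was 53.6-fold higher, so the group test of pyrimidine synthesis holds a change built into the strain and is not given. Of the 7 other measured members URA1 and FUR1 rose (2.16-fold and 2.26-fold). The call of URA1 ended with any of the 6 arrays left out (adjusted p 0.053 to 0.15), and with the values as deposited neither was called (log2 0.23 and 0.30). With the doubtful array out of the fit limma gave URA1 an adjusted p of 0.013. Autophagy had 1 of 8 genes lower there, ATG8. In the group tests of other lists, ribosome biogenesis in N limitation had 4 of 17 genes lower (adjusted p 0.0030; adjusted p = 0.34 with an estimated correlation), single-copy ribosomal proteins were lower in Zn limitation with a median log2 of -0.47 (adjusted p 1.8e-04; adjusted p = 0.29 with an estimated correlation), and anaerobic growth genes were higher by 0.49 in the difference of mutant effects (adjusted p 0.012; adjusted p = 0.18 with an estimated correlation). Between P and S limitation, sterol synthesis had a median log2 of 0.33 (adjusted p 3.7e-04; adjusted p = 0.12 with an estimated correlation), general amino acid control 0.32 (adjusted p 3.7e-04; adjusted p = 0.039 with an estimated correlation) and inositol and choline phospholipid synthesis -0.46 (adjusted p 0.0051; adjusted p = 0.19 with an estimated correlation).

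The second pattern is the 59 genes lower in both mutant groups, which differ from their wild types in deposit as well as genotype. Of the 59, 13 are on the reserve carbohydrate and Msn2/4 lists, GPH1, GSY1, GLC3 and TSL1 among them. As a set these 13 were also lower in the mutants than in S- and P-limited wild type of the same deposit. The median log2 was -1.28 (bootstrap interval over genes -2.00 to -0.99). This interval and the next treat genes as independent and do not measure the spread between cultures. The genes were chosen as low on these same mutant arrays, which favours a low value. Of the 13 genes 9 were at least 2-fold lower, and for 7 all 6 mutant arrays lay below all 6 S- and P-limited arrays. GAC1 and GLG1 were higher in the mutants (0.58 and 0.19). This argues against a difference between deposits as the whole cause for the set, but not for GAC1 and GLG1. The doubtful array was kept in the choice of the genes and in the mutant values. Without it GLG1, PIG2 and GLK1 of the 13 were not called in C limitation (log2 -0.67, -0.82 and -1.06). For the other 46 genes the median was -0.72 (-0.99 to -0.32), with 17 at least 2-fold lower. Deposit and genotype cannot be told apart for these 46 as a set, since the interval reaches above the -0.5 set for this test. MSN2, which the mutant lacks, is one of them (-3.36 or lower, since mutant arrays were at the floor). The nutrient also differs in this comparison, and a dependence of the 13 list members as a set on the msn2 msn4 genotype is a hypothesis from the same data.

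The third pattern is PHO5, at 12 on all 15 wild-type arrays and between 73.7 and 153 on the mutant arrays (log2 at least 3.19, adjusted p 1.0e-08, in C and at least 3.24, adjusted p 6.6e-09, in N limitation). Phosphate starvation of the mutant cultures with no DNA difference is argued against, since PHO5 stayed at the floor in P-limited wild type where PHO84 read at least 3414. Another 14 phosphate regulon genes had median log2 changes of 0.30 and 0.18 in the mutant, with 3 called higher in C limitation (PHO84 3.91-fold, PHO89 3.11-fold, GIT1 at least 2.08-fold) and 2 in N limitation (PHO84 2.18-fold, PHO89 3.43-fold). The calls of PHO89 and GIT1 in C limitation ended in 4 and 5 of the 6 cases of an array left out (adjusted p up to 0.12 and 0.14), and that of PHO84 in N limitation without wild-type replicate 1 (log2 1.00) or mutant replicate 3 (log2 0.99). PHO84 in C and PHO89 in N limitation kept the call in every such case, but not with only the groups compared in the fit. Another acid phosphatase gene, PHO3, was specific to P limitation in wild type, 17.5-fold above the next group. Whether its rise bears on the signal of PHO5 was not tested. A DNA difference at PHO5 between the strains, such that the probe set reads 12 even in P limitation in the wild type, remains a candidate explanation. A change in phosphate regulation beside it stays open, and an effect of the msn2 msn4 genotype on PHO5 was not tested.

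Other splits of the same arrays were tested for the remaining results. With 3 arrays against 3 the 10 splits are too few for a share under 0.05. Every other split also mixes both groups on each side, which widens the spread and keeps its count low in advance. The low counts of other splits therefore do not exclude chance. Real counts of 567, 592, 637 and 806 for N, S, P and Zn against C limitation, 428 for the N-limited mutant and 231 for P against S limitation stood against a highest of 0 genes called by limma in another split, and 220 for the C-limited mutant against 1. Among 100 drawn assignments of the wild-type arrays, the real one included, a share under 0.05 reached the real counts of genes specific to a limitation. For C and N limitation these were 117 (highest other 38, 1 of 100 as large) and 39 (highest other 31, 1 of 100). S limitation had 56 (highest other 154, 3 of 100), P limitation 54 (highest other 0, 1 of 100) and Zn limitation 144 (highest other 42, 1 of 100). Most draws mix limitations within a group, which widens its spread and keeps counts low in advance. The small share therefore does not exclude chance. The larger splits for S limitation put all Zn-limited (154) or all C-limited arrays (99) in its place, so they point to a structure of the samples, the other limitations. For the 19 reserve genes called in at least 1 comparison, 1 of 100 drawn assignments of all arrays was as large (highest other 5), with the same limit. Nor is chance excluded for the 79 list shifts at the preset correlation (highest other 84, 6 of 100).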
